A study of Mus musculus with 12 samples.

How the data were processed

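The data are small RNA sequencing counts from MeCP2 chromatin immunoprecipitates and total chromatin RNA of mouse primary cortical neurons. They come as 1 deposited table of 2240 features by 12 libraries. Its values are counts, which the authors made by mapping reads to GRCm38 with STAR and counting them per gene with featureCounts; edgeR is also named, and no versions are given. The counts are not normalised, replicates are not pooled, and the rule by which the authors chose the listed features is not stated, so features outside the table cannot be assessed. Depolarised neurons named in the series' design are not analysed here.

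Libraries were grouped by fraction (S1 or S2) and kind (IP or input), with 3 in each of the 4 groups. Group assignments, the comparisons, the tests, the gene lists and the alternatives were fixed before the data were examined, except where the text says otherwise. Total counts ranged from 826887 to 23111368. Reads carry no molecular identifiers, so counts of reads are not counts of molecules, and intervals from counting error alone would be too narrow. The values are therefore given with their spread between libraries.

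Features were named as in the table and matched to RefSeq genes of GRCm38 by symbol (1770) or synonym (148); 321 had no match and 1 matched several genes, and coordinates are given only for matched features. Each feature was put in an RNA class from its name and gene type, a grouping made after the data were seen. Mitochondrial features not named as tRNAs were all classed as mitochondrial mRNAs, so that class may hold mitochondrial ribosomal RNA. The prefix planned for spliceosomal snRNAs does not occur in the table, so the names U1, U2, U4, U5, U11, U12 and U4atac were taken in its place. Counts are per gene without strand, so a host gene also counts the small RNA inside it: 334 longer genes hold a small RNA gene or share counts with one, and 20 of these match its counts within 10%. Copies of U RNAs and of some miRNAs are near identical, and how reads were divided among them is not stated.

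Each comparison was a contrast in a single edgeR quasi-likelihood fit of all 12 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3). It used TMM factors, the filterByExpr filter, which left 2239 features, robust estimation and no replicate block. Tests were two-sided, with Benjamini-Hochberg adjustment over the features of a comparison and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. The 5 comparisons were IP against input in S1 and in S2, their difference, and S2 against S1 in input and in IP. Lists of genes were tested with camera at its preset correlation of 0.01, with adjustment over 11 lists and 5 comparisons (55 tests), and again with an estimated correlation and with fry. Of 15 lists, those with fewer than 3 members were not tested. Lists can share members, so their results are not independent of each other. RNA classes were tested in the same way over 75 tests, chosen after the data were seen. The median log2 count of miRNA and snRNA features (with 0.5 added) was also taken relative to that of all tested features in each library. Shares and these values were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

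The named features follow a fixed rule. It considers features past the threshold with a mean of at least 10 CPM (counts scaled to library size and TMM factor) in the higher group. Of these it takes the 10 (for IP against input) or 5 (for the other comparisons) with the largest change in each direction. Where fewer than 5 pass, those with the smallest p fill the number up to 5. From each list it takes up to 4 members with the smallest p, and it adds the 5 most abundant features. Of the list members only some are printed, and some were left out after it was seen that their sign changes under an alternative.

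The procedure was tested on simulated data with 200 features changed by known folds. At 8-fold, 77.6% of changed features were called for IP against input in S1, 84.0% in S2, 34.0% for the difference, 80.0% for S2 against S1 in input and 86.0% in IP; at 4-fold these were 40.0%, 38.8%, 8.00%, 44.0% and 48.0%. Between 2.55% and 8.33% of calls were unchanged features. The changed features were drawn at random from all features and simulated independently of each other. The shares called therefore need not hold for miRNAs or snoRNAs. In S1 the median SE was 0.91 for miRNAs and 1.08 for box C/D snoRNAs, against 0.49 for genes for proteins.

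Alternatives were RLE and upper-quartile factors, library sizes alone, DESeq2 1.42.0, no filter, a minimum mean of 10 CPM, only the groups compared, the replicate number as a block, the most abundant feature left out, copies of a miRNA summed, a non-robust fit and each of the 12 libraries left out. The minimum of 10 CPM in this filter used library sizes without TMM factors. Others were added after the data were seen: small RNA features alone, longer genes holding small RNAs left out, miRNA features alone (for counts of calls only, since single values are then relative to the miRNA mean by construction), TMM factors from box C/D snoRNAs alone, and S2 libraries alone with a replicate block. Figures were drawn with matplotlib 3.10.9.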

Results

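Small RNA recovered with MeCP2 from chromatin was measured in mouse cortical neurons grown for 6 days in vitro. MeCP2 is a nuclear protein that binds methylated DNA and is abundant in neurons. Chromatin was digested with 250 units of micrococcal nuclease (MNase, which cleaves DNA between nucleosomes) for 12 min. It was then separated into S1, the nuclease-sensitive fraction rich in mononucleosomes, and S2, the nuclease-resistant fraction of oligonucleosomes. From each fraction, RNA recovered with an anti-MeCP2 antibody (IP) and total chromatin RNA of the same fraction (input, the background) were sequenced as small RNA. There were 3 libraries in each of the 4 groups, 12 in all, and none was from depolarised cells. No library came from an IP with a control antibody, so RNA bound to MeCP2 cannot be told apart from other RNA recovered in the IP. Counts summed to 10434621, 826887 and 15094882 in S1 input replicates 1 to 3, and to 12531151, 4943590 and 3209693 in S1 IP. They summed to 12353855, 10554043 and 21423308 in S2 input, and to 6483996, 5855013 and 23111368 in S2 IP. Nothing in the labels says whether replicates came from separate cultures, so each p-value measures the spread between these libraries, which may be technical.

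Box C/D snoRNAs, which guide 2'-O-methylation of ribosomal RNA, took the largest share of the counts in every group. Their mean share was 41.9% ± 17.8 (SD, n = 3) in S1 input, 56.6% ± 2.73 in S1 IP, 56.2% ± 0.103 in S2 input and 56.3% ± 0.781 in S2 IP. The most abundant features in the summed counts of the 12 libraries were Gas5, a non-coding RNA whose introns encode snoRNAs, with 15.0% of all counts, SNORD74 with 10.5%, AC025794.1 with 6.57%, and Rpl13 and Snord68 with 3.54% each. In single libraries the share ran from 3.51% to 21.5% for Gas5 and from 0.930% to 18.6% for SNORD74. Rpl13 encodes a ribosomal protein and holds Snord68, so the same reads stand behind both. The count of Gas5 can likewise include reads of the snoRNAs in its introns, so its share is not that of the non-coding RNA alone and may overlap with theirs. The 10 most abundant features of each library held 54.2% ± 8.86 of its counts in S1 input, 45.8% ± 6.51 in S1 IP, 50.9% ± 3.42 in S2 input and 55.2% ± 1.86 in S2 IP. The exact two-sided permutation p of these shares was 0.3 for IP against input in S1, 0.1 in S2, 0.6 for S2 against S1 in input and 0.1 in IP, where 0.1 is the smallest that 3 against 3 libraries can give. The gap in S2 changed direction when only the top feature was taken (-0.562 percentage points), and that between the inputs when the top 50 were taken (3.75). S1 input replicate 2 stood apart. It had the fewest counts and a TMM factor of 6.05, and genes for proteins without a small RNA gene inside took 21.8% of it. Its correlation of log2 CPM (counts scaled to library size and TMM factor) with the other S1 input libraries was 0.755 and 0.738 across features. This compares with 0.96 between those libraries, and with 0.836 and 0.796 between S1 input replicate 2 and S1 IP replicates 2 and 3.

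With the given labels, miRNAs took a smaller share of the counts in the MeCP2 IP of S1 than in its input, and a smaller share in S2 than in S1. They took 6.46% ± 2.51 (SD, n = 3) of the counts in S1 input, 2.48% ± 1.07 in S1 IP, 0.483% ± 0.231 in S2 input and 0.409% ± 0.295 in S2 IP. Every S1 IP library lay below every S1 input library, and every S2 library below every S1 library of its kind. The exact two-sided permutation p was 0.1 for each of these, the smallest that 3 against 3 can give, and 0.7 for IP against input in S2. Adjusted over all classes and comparisons, the 0.1 became 0.278. Without S1 input replicate 2, the S1 input share was 5.39% ± 2.39 (n = 2). If the labels of S1 input replicate 2 and S1 IP replicate 1 were exchanged, which the correlations leave open, the S1 means would be 4.03% in input and 4.91% in IP.

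**Figure D1:**
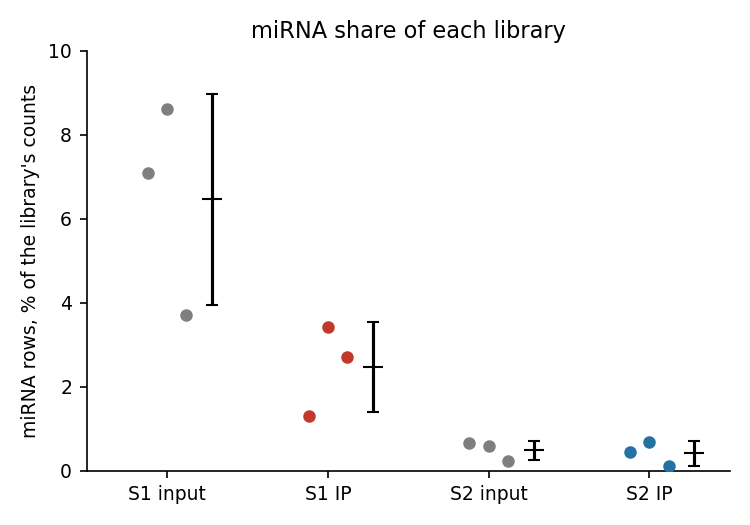
Share of each library's counts in miRNA features (%, vertical axis) by group (horizontal axis), with points for the 3 libraries of a group and a bar for their mean ± SD. The means were 6.46% in S1 input, 2.48% in S1 IP, 0.483% in S2 input and 0.409% in S2 IP.

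The comparison of IP with input in S1 asks which RNAs are recovered with MeCP2 from open chromatin. MicroRNAs and snRNAs had the lowest class medians in the MeCP2 IP with the given labels; with those 2 labels exchanged, the snRNA median (-1.86) lay above that of box C/D snoRNAs (-2.21). Of 206 miRNA features 204 were lower, with a median log2 fold change of -2.72, and all 30 snRNA features were lower, with a median of -2.38. As classes they passed by camera (adjusted p = 3.40e-53 and 1.49e-23), and not with an estimated correlation (0.542 and 0.473) or by fry (0.452 and 0.0532). Genes for proteins lay near 0 (median 0.14 over 1552 features). As most of the 2239 features they largely set the TMM scaling, so this does not show that IP left them unchanged. In all, 23 of 2239 features passed the edgeR test at an adjusted p of 0.05, 22 of them lower and 1 higher in IP. The lower ones were 9 snRNAs, 7 genes for proteins, 5 miRNAs and 1 box H/ACA snoRNA.

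Among those that fell, Mir9-3, a copy of the neuronal miR-9 gene on chromosome 7 (GRCm38, 79505264 to 79505353), went from a mean of 25.6 ± 17.7 (SD, n = 3) to 1.60 ± 0.463 CPM, a log2 fold change of -3.98 ± 0.60 (SE) with an edgeR adjusted p of 0.00394. Mir212, an activity-responsive miRNA on chromosome 11 (75173388 to 75173478), fell by 2.73 ± 0.60 on the log2 scale. Mir339 (-3.67 ± 0.83), Mir2137 (-3.60 ± 0.64) and Mir181b-1 also fell. U4atac, an RNA of the minor spliceosome (ENSMUSG00000080542), went from 175.7 ± 126 to 6.33 ± 3.49 CPM (log2 fold change -4.79 ± 0.91, edgeR adjusted p = 0.0222). Both copies of U4 fell, with -4.08 ± 0.88 (ENSMUSG00000096243) and -3.97 ± 0.79 (ENSMUSG00000094377). Of the genes for proteins, Xylb, which encodes xylulokinase (chromosome 9, 119357381 to 119393797), had the lowest adjusted p of all features (log2 fold change -4.81 ± 0.59, edgeR adjusted p = 0.00109). Fgg, the fibrinogen gamma chain, had -5.18 ± 1.11, Car9, a carbonic anhydrase, -4.96 ± 1.07, and Bcorl1, a transcriptional corepressor, -3.37 ± 0.71, all with an edgeR adjusted p of 0.0407. SNORA50 fell by 3.61 ± 0.82. Without S1 input replicate 2, Car9 had -3.21 and Bcorl1 -1.87. The higher feature, Fcho2 (log2 fold change 1.79, edgeR adjusted p = 0.0441), was under 10 CPM and is named after its values were seen. Of the other higher features with at least 10 CPM, those with the smallest p did not pass. SNORD94 had a mean of 1501 ± 706 CPM in input and 11624 ± 6223 in IP (log2 fold change 2.95 ± 0.93, edgeR adjusted p = 0.125), and SNORA71, Hnrnpm, Lipe and SNORA5 had 2.11 ± 0.68, 1.38 ± 0.47, 2.23 ± 0.79 and 1.34 ± 0.48.

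Camera compares each list with all other features, so a miRNA list can pass because miRNAs as a class were lower (median -2.72). The miRNA list values below therefore do not set a list apart from other miRNAs. Of the lists, spliceosomal snRNA, whose members were named after the table was seen, had the smallest camera adjusted p in S1, although 6 miRNA lists had lower medians. Its 29 members were all lower in IP (median -2.30), 9 passed over all features and 23 adjusted over the list alone; the camera adjusted p was 4.56e-22, and 0.248 with an estimated correlation. Of 14 neuron-enriched miRNAs (median -2.57), 2 passed, Mir9-3 and Mir212, and 12 adjusted over the list alone, while Mir218-2 had -2.96 ± 0.76 and Mir137 -2.27 ± 0.69 (camera adjusted p = 2.84e-08, or 0.248 with an estimated correlation). The 24 members of the imprinted miR-379/miR-410 cluster (median -2.84) had 0 calls, and 21 adjusted over the list alone, with Mir329 at -3.08 ± 0.75, Mir494 at -2.83 ± 0.72, Mir679 at -3.24 ± 0.85 and mmu-mir-380 at -3.42 ± 0.93 (camera adjusted p = 5.32e-10, or 0.305). The 10 miRNAs linked to MeCP2 in earlier work (median -2.85) had 0 calls and 10 adjusted over the list alone (camera adjusted p = 6.44e-06, or 0.293 with an estimated correlation); Mir182 had -3.25 ± 0.97 and Mir383 -2.84 ± 0.93. The 7 activity-responsive miRNAs had a median of -2.86, with 1 call, Mir212, and 7 adjusted over the list alone, and Mir138-1 at -2.89 ± 0.93 (camera adjusted p = 7.87e-06, or 0.248). The 13 let-7 family features had a median of -1.71, 0 calls and 5 adjusted over the list alone, with mmu-let-7f-1 at -2.47 ± 0.66 and Mirlet7i at -2.92 ± 1.06 (camera adjusted p = 7.87e-06, or 0.334). The 9 features of the miR-17/92 clusters, known from proliferating cells, had a median of -2.77, 0 calls and 9 adjusted over the list alone, with Mir19a at -3.27 ± 0.89 and Mir92-2 at -3.04 ± 0.84 (camera adjusted p = 4.16e-05, or 0.305).

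Markers of other cell types went the same way in S1. The 4 glial miRNAs had a median of -3.05, 0 calls and 4 adjusted over the list alone (camera adjusted p = 0.000449, or 0.248 with an estimated correlation), with Mir146 at -3.67 ± 0.93 and Mir21 at -3.24 ± 1.07. Endothelial Mir126 and vascular Mir143 had -2.93 ± 0.75 and -3.18 ± 1.12, and Mir192, found in liver and gut, -2.30 ± 0.77; these lists had 2 members each and were not tested. Blood and muscle markers had 0 members in the file. The 5 entries likely to be fragments of ribosomal or transfer RNA had a median of -1.98, with 1 call, Mir2137, and 3 adjusted over the list alone (camera adjusted p = 0.000151, or 0.248), and Mir1983 had -2.01 ± 0.69. The 3 mirtrons had -1.91, 0 calls and 0 adjusted over the list alone (camera adjusted p = 0.0346, or 0.380), and Mir1224 had -1.91 ± 0.77. The 278 snoRNAs did not pass (median -0.72, camera adjusted p = 0.134, 1 call and 0 adjusted over the list alone). Their median was 0.26 with upper-quartile factors, 0.36 with library sizes alone and 0.70 among small RNA features alone; SNORD113 (ENSMUSG00000064487) had -3.65 ± 0.93.

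The scaling sets the size of these values. The median of all features in S1 lay at -0.03 with TMM, 0.58 with upper-quartile factors, -0.29 with library sizes alone and -1.0 with factors from box C/D snoRNAs, and relative to it the miRNA median was -2.69, -2.32, -1.0 and -0.87 and the snRNA median -2.35, -2.08, -1.59 and -1.64. The count of 23 rests on single libraries. It was 253 (240 lower) without S1 input replicate 2, with all 23 among them, 10 and 12 without S1 input replicates 1 and 3, 2, 4 and 3 without S1 IP replicates 1, 2 and 3, 11 and 9 without S2 input replicates 1 and 2, and 6, 6 and 10 without S2 IP replicates 1, 2 and 3; DESeq2 called 232.

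**Figure D2:**
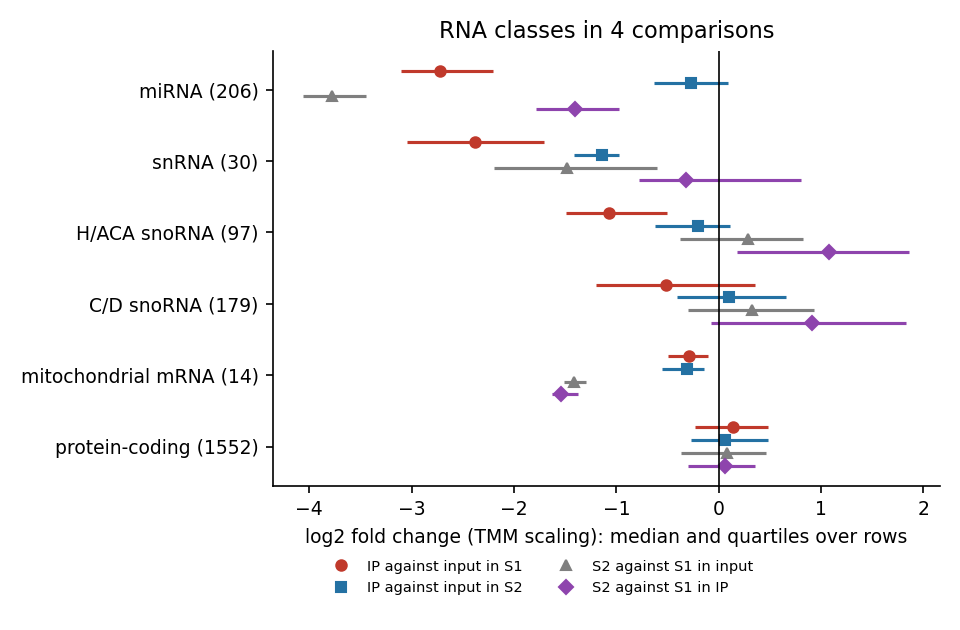
Median log2 fold change of 6 RNA classes (horizontal axis, TMM scaling; number of features in brackets), with a symbol per comparison and lines from the lower to the upper quartile over features. miRNA medians were -2.72 for IP against input in S1, -0.27 in S2 (0.08 with factors from box C/D snoRNAs), -3.78 for S2 against S1 in input and -1.40 in IP; the sign of the snoRNA medians depends on the scaling.

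The copies of each U RNA were summed, 6 of U1, 11 of U2, 2 of U4 and 7 of U5; U11, U12 and U4atac have 1 each and stay as they were. Since every copy was below 0 in S1, so were the sums. U4atac had -4.80 ± 0.92 and was the one with an edgeR adjusted p under 0.05 over all features (0.0340), followed by U4 with -4.06 ± 0.90, U1 with -2.83 ± 0.90, U12 with -2.51 ± 0.83, U2 with -1.94 ± 0.78, U11 with -1.69 ± 0.77 and U5 with -1.57 ± 0.96. Adjusted over these 7 alone, all but U5 (edgeR adjusted p = 0.122) passed. In S2 the 7 values ran from -2.19 (U1) to -0.24 (U11), and none passed. The camera p of the 7 as a set was 5.58e-09 in S1 (0.0207 with an estimated correlation) and 0.000189 in S2 (0.104).

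**Figure D3:**
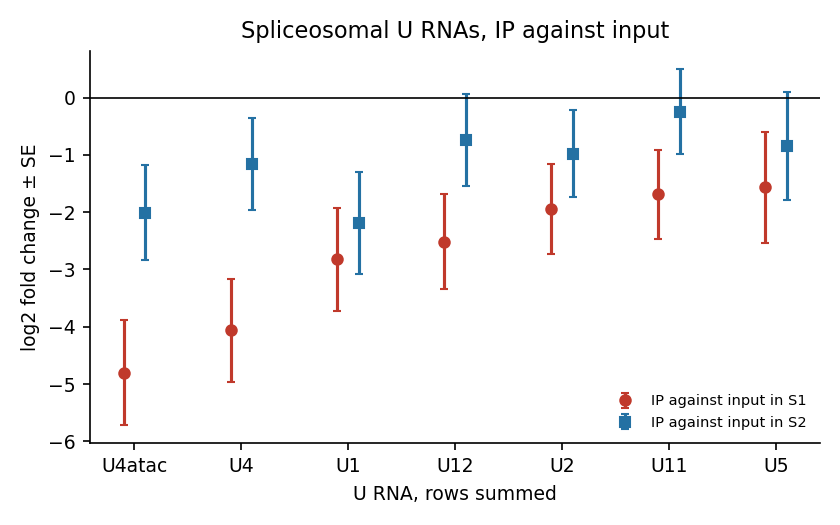
Log2 fold change ± SE of IP against input (vertical axis) for 7 spliceosomal U RNAs with their copies summed (horizontal axis), in S1 and in S2. All 14 values lie below 0, from -4.80 (U4atac) to -1.57 (U5) in S1 and from -2.19 (U1) to -0.24 (U11) in S2.

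The same comparison in S2 asks about closed chromatin. There, miRNAs differed little between the MeCP2 IP and its input, while the spliceosomal snRNAs stood lower in IP as a set by camera at its preset correlation (adjusted p = 2.16e-11), and not with an estimated one (0.248). The median log2 fold change was -0.27 over the 206 miRNA features (143 below 0) and -1.14 over the 30 snRNA features (28 below 0). U1 copies had -2.92 ± 1.03 (ENSMUSG00000095616) and -2.48 ± 0.90 (ENSMUSG00000096349), and U4atac had -2.01 ± 0.81. No feature passed the edgeR test (0 of 2239, smallest adjusted p 0.999); 85 had an unadjusted p under 0.05, and DESeq2 also called 0. The miRNA median was 0.14 without S2 input replicate 2 and 0.08 with factors from box C/D snoRNAs. The median of all features shifted to -0.28 with library sizes alone, -0.13 with upper-quartile factors and 0.35 with box C/D factors, relative to which the snRNA median was -1.21, -1.15 and -1.09.

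By list, the 29 spliceosomal snRNAs had a median of -1.14 in S2, with 27 below 0. All 13 let-7 features were below 0 (median -0.69, camera adjusted p = 0.00363, or 0.507 with an estimated correlation), and Mirlet7a-1 had -1.38 ± 0.59. The snoRNA list passed as lower (camera adjusted p = 0.0187, or 0.879) on a median of -0.05, a sign that changes to 0.04 among small RNA features alone; Snord22 had -2.26 ± 0.97. The other lists did not pass. The neuron-enriched miRNAs had a median of 0.07, the miR-379/miR-410 cluster -0.22, the miRNAs linked to MeCP2 -0.23, the activity-responsive ones -0.14, the miR-17/92 clusters -0.45, the mirtrons -0.39, the glial markers -0.06 (with a test direction of higher) and the rRNA or tRNA fragments 0.10 (mean -0.06). All of these but the miR-17/92 clusters change sign under at least 1 scaling. Adjusted over the list alone, 0 features passed in any list. The features with the smallest p were, among the higher, Gm17615 (2.13 ± 0.54), AC171211.1 (2.66 ± 0.69), Caps2 (2.53 ± 0.80), Icmt (4.14 ± 1.33) and Tsga10 (1.28 ± 0.46), and, among the lower beside the U RNAs, AC123795.1 (-1.30 ± 0.51) and Rheb (-1.21 ± 0.49). Icmt rests on S2 IP replicate 1, with 976 counts there against 28 and 9.

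In S2, each input library had its best match among the IP libraries in its own replicate number (correlations across features of 0.297, 0.441 and 0.472 after group means were removed). In S1 this held for replicate 1 (0.685) but not for replicates 2 (0.276) and 3 (-0.116). A fit of the S2 libraries alone with the replicate number as a block, chosen after the data were seen, called 21 features, 10 higher and 11 lower in IP. AC171211.1 (2.69 ± 0.37, edgeR adjusted p = 5.45e-04), Gm17615 (2.18 ± 0.37), Caps2 (2.65 ± 0.47) and Kpna1, a nuclear import receptor (1.70 ± 0.33), rose. U1 (ENSMUSG00000095616, -2.78 ± 0.49), U4atac (-1.98 ± 0.37), 5S_rRNA (-3.32 ± 0.56) and Gm15280 (-3.04 ± 0.46) fell. Kpna1 (2.60 CPM in input and 8.11 in IP), 5S_rRNA (4.73 and 0.465) and Gm15280 (6.08 and 0.678) had means under 10 CPM in both groups. The block in the fit of all 12 libraries called 0, and in each other comparison the best match had the same number for 1 of 3 replicates.

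Whether the effect of IP differed between S2 and S1 was tested as an interaction. The miRNAs were the class with the largest difference: 202 of 206 had a higher IP to input ratio in S2 than in S1, with a median difference of 2.35 on the log2 scale. The snRNAs had a median difference of 1.01 (28 of 30). Mir9-3 had 4.01 ± 0.82, Xylb 4.35 ± 0.80 and a U1 copy (ENSMUSG00000065371) 3.91 ± 0.82, each with an edgeR adjusted p of 0.119; Mir126, in the intron of Egfl7, had 4.42 ± 1.05, and Obsl1 2.52 ± 0.66. On the other side, SNORD94 had -3.93 ± 1.27, Snord22 -2.80 ± 1.34, Myh4 -2.48 ± 1.22, Lrrc17 -1.79 ± 0.93 (0.62 with box C/D factors) and SNORA71 -1.70 ± 0.92. No feature passed (0 of 2239 by edgeR, with 99 at an unadjusted p under 0.05), while DESeq2 called 7. Leaving out S1 input replicate 2 gave 22 calls, all of them higher in S2, and leaving out S2 input replicate 2 gave 1. The median of all features, 0.07 with TMM, shifted to -0.70 with upper-quartile factors and 1.40 with box C/D factors, relative to which the miRNA median was 1.96 and 0.53.

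Total chromatin RNA of S2 was compared with that of S1 to describe the background. Almost every miRNA was lower in the closed fraction: 204 of 206 were below 0, with a median log2 fold change of -3.78, and 177 passed. In all, 242 of 2239 features passed the edgeR test, 238 lower and 4 higher in S2. Beside the miRNAs, the lower ones included 34 genes for proteins, 9 snRNAs, 4 scaRNAs and 4 long non-coding RNAs. All 14 features of the mitochondrial mRNA class, which may include ribosomal RNA, were below 0 (median -1.41, 1 called). So were the 3 Y RNAs, small cytoplasmic RNAs (median -2.98, 0 called). By camera, these classes had an adjusted p of 0.000844 and 0.00805, but 0.873 and 0.487 with an estimated correlation.

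The called features with the largest falls were Gyltl1b (now Large2, a glycosyltransferase gene; -7.64 ± 1.93), Car9 (-5.82 ± 1.11), Mir1298 (-5.64 ± 1.27), Mir448 (-5.19 ± 1.09) and Mir204 (-5.16 ± 1.30). Mir1298 and Mir448 lie in introns of the serotonin receptor gene Htr2c on the X chromosome, and Mir1298 went from 381 ± 478 (SD, n = 3) to 7.65 ± 3.67 CPM. Gyltl1b rests on S1 input replicate 2, with 1341 counts there against 8 and 1. Without that library it had -0.95 and did not pass (edgeR adjusted p = 0.683). Mir204 had -2.38 without S1 input replicate 3 and did not pass there (edgeR adjusted p = 0.104). The 4 higher features, snoU6-53, AC132131.1, Myo9b and Fcho2, were under 10 CPM and are named after their values were seen; the last 3 are lower with box C/D factors. Above that level, Pcm1 (1.15 ± 0.49), SNORD127 (2.52 ± 1.08), Snord8 (1.89 ± 0.85), Kalrn (1.22 ± 0.55) and SNORA62 (2.02 ± 0.97) had the smallest p among higher features and did not pass; Pcm1 and Kalrn are lower with library sizes alone.

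Every miRNA list was lower in S2 input by camera, each with an adjusted p of 0.248 with an estimated correlation. The miRNA class as a whole had a median of -3.78, and camera compares a list with all other features. These values therefore do not set a list apart from other miRNAs. In the let-7 family 13 of 13 passed as lower (median -3.51, 13 adjusted over the list alone, camera adjusted p = 1.73e-12), with mmu-let-7f-1 at -3.53 ± 0.70 and Mirlet7a-1 at -2.38 ± 0.54. In the miR-379/miR-410 cluster all 24 were below 0 and 21 passed (median -3.66, 23 adjusted over the list alone, camera adjusted p = 7.41e-15), with Mir329 at -3.85 ± 0.79, Mir494 at -3.73 ± 0.76 and mmu-mir-380 at -4.61 ± 0.99. Of the 14 neuron-enriched miRNAs 13 were below 0 and 10 passed as lower (median -3.83, 12 adjusted over the list alone, camera adjusted p = 2.41e-09), among them Mir9-3 (-3.96 ± 0.59), Mir218-2 (-4.25 ± 0.81) and Mir149 (-3.94 ± 0.99). All 7 activity-responsive miRNAs passed as lower (median -3.85, 7 adjusted over the list alone, camera adjusted p = 3.20e-07), including Mir132 (-4.23 ± 1.09) and Mir212 (-3.94 ± 0.64). Of the 10 linked to MeCP2, all were below 0 and 8 passed (median -3.63, 10 adjusted over the list alone, camera adjusted p = 3.20e-07), including Mir383 (-4.06 ± 0.99) and Mir182 (-3.96 ± 1.02). In the miR-17/92 clusters all 9 were below 0 and 8 passed (median -3.99, 9 adjusted over the list alone, camera adjusted p = 1.84e-06), with Mir106b at -4.49 ± 1.13 and Mir92-2 at -3.99 ± 0.88. Without S1 input replicate 3, Mir92-2 had -2.38 and did not pass (edgeR adjusted p = 0.0920). All 3 mirtrons were below 0 and 2 passed (median -3.17, 3 adjusted over the list alone, camera adjusted p = 0.00194), with Mir1224 at -3.17 ± 0.83.

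Markers of other cell types fell with them. All 4 glial miRNAs passed (median -4.19, 4 adjusted over the list alone, camera adjusted p = 5.18e-05), with Mir146 at -4.34 ± 0.96 and Mir219-1 at -4.22 ± 0.95, as did Mir126 (-3.84 ± 0.79), Mir143 (-4.13 ± 1.17), Mir192 (-3.74 ± 0.83) and the liver miRNA Mir122a (-2.22 ± 0.66). Without S1 input replicate 3, Mir143 had -2.66 and did not pass (edgeR adjusted p = 0.165). Of the 5 likely rRNA or tRNA fragments all were below 0 and 3 passed (median -2.94, 5 adjusted over the list alone, camera adjusted p = 1.37e-05), Mir2137 with -3.70 ± 0.64. Of the 29 spliceosomal snRNAs 23 were below 0 and 8 passed as lower (median -1.45, 13 adjusted over the list alone, camera adjusted p = 4.59e-06, or 0.317 with an estimated correlation), U1 (ENSMUSG00000065371) with -4.08 ± 0.56, another U1 (ENSMUSG00000065017) with -2.54 ± 0.53 and U4atac with -3.55 ± 0.85. The 278 snoRNAs were higher as a set (median 0.29, camera adjusted p = 2.12e-05, or 0.693 with an estimated correlation, and -0.31 with box C/D factors), although 101 of them were below 0. Over all features 6 passed as lower, and 1 passed adjusted over the list alone. SNORA12 had -2.64 ± 0.51 and SCARNA16 -3.76 ± 0.88.

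The median of all features shifted from -0.01 with TMM to 0.71 with upper-quartile factors, -1.50 with library sizes alone and -2.44 with box C/D factors, relative to which the miRNA median was -3.77, -3.44, -1.89 and -1.59, and the called features split into 42 higher and 125 lower with upper-quartile factors. The count of 242 became 96, 62, 8, 95 and 5 without S1 input replicates 1 and 3 and S2 input replicates 1, 2 and 3, and 6 in a fit of the 6 input libraries alone; it shares the S1 input with the IP comparison in S1, and of the 22 features lower there 18 were also lower here, against 2.34 expected of independent lists. Part of this may come from the shared libraries: the log2 fold changes of the 2 comparisons correlated at 0.795 across features, and at 0.511 in simulations without any change. The simulations gave all groups the same spread and drew features independently, so 0.511 may be too low a reference for these libraries.

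The IPs of S2 and S1 were compared directly to ask where the RNA recovered with MeCP2 differs between closed and open chromatin. This contrast also carries the difference between the inputs. The let-7 family was lower in S2 IP by camera at its preset correlation (adjusted p = 5.08e-14), and not with an estimated one (0.248), with 0 features called over all features. All 13 were below 0 (median -2.23), with Mirlet7a-1 at -2.68 ± 0.59, and miRNAs as a class had a median of -1.40 (195 of 206 below 0). Both medians were lower still between the inputs (-3.51 and -3.78). The IP to input ratio was thus higher in S2 than in S1 for let-7 and for miRNAs (median differences 1.28 and 2.35). SNORD94, a guide for modification of U6, had the smallest p (-5.30 ± 1.04, edgeR adjusted p = 0.243), with a mean of 11624 ± 6223 (SD, n = 3) CPM in S1 IP and 294 ± 122 in S2 IP. SNORA5 had -1.99 ± 0.50, the RNase P RNA -3.47 ± 0.93, snoU109 -3.21 ± 0.86 and SCARNA16 -2.92 ± 0.85. Higher values were those of SNORD113 (ENSMUSG00000064720, 3.86 ± 1.21), Snord123 (4.71 ± 1.53), 2310045N01Rik (now Borcs8; 2.46 ± 0.82), Snora73a (3.22 ± 1.15) and Icmt (3.83 ± 1.31).

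No feature passed in this comparison (0 of 2239 by edgeR, 163 at an unadjusted p under 0.05), while DESeq2 called 13, and 2 passed without S1 input replicate 2. Of the let-7 features 11 passed adjusted over the list alone. By camera, the miR-379/miR-410 cluster had an adjusted p of 1.14e-06 (median -1.16, or 0.387), the miR-17/92 clusters 0.00185 (median -1.59, or 0.380), the miRNAs linked to MeCP2 0.00633 (median -1.03, or 0.454), the activity-responsive ones 0.00667 (median -1.18, or 0.404), the mirtrons 0.00743 (median -1.65, or 0.305), the neuron-enriched 0.0221 (median -1.11, or 0.469), the glial 0.0450 (median -1.02, or 0.448) and the rRNA or tRNA fragments 0.0481 (median -0.86, or 0.448); the value after each median is the adjusted p with an estimated correlation. Adjusted over the list alone, these 8 lists had 0 calls each. Camera set them against all other features and not against the miRNA class, whose median was -1.40. The snoRNAs were higher (median 0.89, camera adjusted p = 8.06e-09, or 0.549 with an estimated correlation, 1 adjusted over the list alone), but their median was -0.57 with library sizes alone and -0.01 with box C/D factors, under which the median of all features shifted to -1.36 and -0.96. The spliceosomal snRNAs did not pass (median -0.20, camera adjusted p = 0.956, 0 adjusted over the list alone).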

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

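Tests chosen only after the result was seen were those of RNA classes, of ratios to box C/D snoRNA counts or to the median of all features within libraries, of mitochondrial mRNAs and Y RNAs in S1, of exchanged labels in S1, of summed U RNAs with several copies (in place of a planned count of lower sums, which the signs of the copies had fixed), and of S2 libraries with a replicate block; the list tests (apart from the members of the spliceosomal snRNA list, named after the table was seen), the splits of the libraries and the test of mitochondrial mRNAs between the inputs were planned.

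At its preset correlation, a camera test of the interaction itself called the effect of IP different between the fractions for 9 lists and 3 classes, which is why they stand here; with an estimated correlation 0 of them passed (list adjusted p 0.248 to 0.593), and by fry 0 of the 9 lists did (adjusted p 0.148 to 0.512). In each the IP to input ratio was higher in S2 unless stated. The camera adjusted p was 2.66e-09 for the miR-379/miR-410 cluster (median difference 2.51 on the log2 scale, 24 of 24 members above 0), 1.52e-08 for neuron-enriched miRNAs (2.63, 13 of 14), 1.14e-06 for spliceosomal snRNAs (0.97, 27 of 29), 8.95e-06 for miRNAs linked to MeCP2 (2.57, 10 of 10), 1.26e-05 for activity-responsive ones (2.59, 7 of 7), 0.000135 for glial ones (3.19, 4 of 4), 0.000151 for the miR-17/miR-92 clusters (2.36, 9 of 9), 0.000993 for rRNA or tRNA fragments (2.08, 5 of 5) and 0.0166 for let-7 (1.28, 12 of 13). Adjusted over the list alone, 1 feature passed among the neuron-enriched, 1 among the spliceosomal snRNAs, 2 among the activity-responsive, 3 among the glial and 1 in the miR-17/miR-92 clusters, and 0 in the others. Mirtrons (camera adjusted p = 0.130) and snoRNAs (0.972) did not pass. The lists are not separate lines of evidence, since they can share members, as the neuron-enriched and activity-responsive lists share Mir212. Camera set each miRNA list against all other features and not against the miRNA class, whose median is given next. Of the classes, miRNAs had a camera adjusted p of 4.43e-43 (median 2.35), snRNAs 6.67e-07 (1.01) and genes for proteins 4.93e-10, tested as lower on a median of -0.09 and a mean of 0.04, which differ in sign; with an estimated correlation these became 0.542, 0.571 and 0.547. On the ratio of miRNA to box C/D snoRNA counts, the difference between the fractions was 1.47 with a permutation p of 0.335.

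Regrouping the libraries at random shows how far such calls can arise without the groups. Of 100 regroupings of the 12 libraries, the real one included, 30 gave at least the 43 list calls (of 55) found here, and the highest other gave 55, so chance cannot be excluded for the list calls at the preset correlation. For the interaction, 100 of 100 gave at least the real count of 0, the highest other 328. Any regrouping reaches a count of 0, so the 100 of 100 was fixed in advance and decides nothing. For IP against input in S1, 2 of the 10 splits gave at least 23 features, and the highest other gave 345. That split exchanges S1 input replicate 2 and S1 IP replicate 1 and called 140 miRNAs and 63 box C/D snoRNAs lower, which points to a structure of the samples. For S2 against S1 in input, 1 of 10 splits gave at least 242, and the highest other 172. For IP against input in S2 and for S2 against S1 in IP, 10 of 10 gave at least the real count of 0, with 0 as the highest other. The 10 of 10 was likewise fixed by the real count of 0. In S2 with the replicate block, 1 of the 4 ways to exchange labels within pairs gave at least 21 features, and the highest other gave 1. With 10 or 4 splits a share under 0.05 cannot be reached.

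With the given labels, miRNAs were lower in S1 IP than in S1 input (median log2 fold change -2.72, 204 of 206, 5 called; camera adjusted p = 3.40e-53, but 0.542 with an estimated correlation and 0.452 by fry). Whether scaling is the whole cause depends, with these labels, on the reference taken within each library. The log2 ratio of miRNA to box C/D snoRNA counts, which no scaling changes, differed by -1.95 on average (-1.27 without S1 input replicate 2). Every IP library lay below every input library (exact permutation p = 0.1, the smallest possible). Relative to the median of all features, which no scaling changes either, the groups overlapped (-2.06, exact permutation p = 0.4) unless S1 input replicate 2 was left out (-3.37). The first measure argues against scaling as the whole cause and the second does not decide it, and both were chosen after the data were seen. Exchanged labels of S1 input replicate 2 and S1 IP replicate 1 stay open. Across features the former correlated better with S1 IP replicates 2 and 3 (0.836 and 0.796) than with S1 input replicates 1 and 3 (0.755 and 0.738). S1 IP replicate 1 correlated slightly better on average with those inputs (0.933 and 0.916) than with those IPs (0.950 and 0.857). With the labels exchanged the TMM median of miRNAs was -2.94, against -2.21 for box C/D snoRNAs and -1.86 for snRNAs. The miRNA difference relative to the median of all features became -2.83, and the groups no longer overlapped. By contrast, the difference in the box C/D ratio turned to 0.85 and the mean share of counts was higher in IP (4.91%) than in input (4.03%). Cytoplasmic and mitochondrial RNA carried into the S1 input cannot be told apart from an effect of IP, because the libraries spread too widely: with TMM, mitochondrial mRNAs had a median of -0.29 and Y RNAs -0.36, while relative to box C/D snoRNA counts mitochondrial mRNAs differed by -1.39 (0.34 without S1 input replicate 2) and Y RNAs, which go against it, by -0.024 (1.11 without that library). These ratios were added to the criterion after the values were seen, and without them the test would have argued against carry-over; weaker binding of miRNAs by MeCP2 than of other chromatin RNA also stays open and was not tested.

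MicroRNAs were lower in S2 input than in S1 input (median -3.78, 204 of 206, 177 called; camera adjusted p = 3.99e-92, but 0.473 with an estimated correlation and 0.169 by fry). The ratio to box C/D snoRNA counts was lower in S2 by a difference of -4.34 (exact permutation p = 0.1, the smallest possible, and -3.66 without S1 input replicate 2). Relative to the median of all features the groups overlapped (-3.23, exact permutation p = 0.2) unless S1 input replicate 2 was left out (-4.54). The first measure argues against scaling as the whole cause and the second does not decide it with all libraries, and both were chosen after the data were seen. Cytoplasmic and mitochondrial RNA in the S1 fraction may contribute: without S1 input replicate 2, mitochondrial mRNAs had a median of -1.64, with 14 of 14 below 0, and Y RNAs -3.40. A difference between open and closed chromatin in the miRNA they hold stays open and was not tested apart from this.

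Spliceosomal snRNAs were lower in IP than in input by camera at its preset correlation, but had an adjusted p of 0.248 with an estimated one in S1 (9 of 29 called) and in S2 (0 called, also adjusted over the list alone). The fit of the S2 libraries alone with a replicate block, chosen after the data were seen, did call some of them lower. These were U4atac (-1.98) and the U1 copies ENSMUSG00000095616 (-2.78), ENSMUSG00000096349 (-2.46) and ENSMUSG00000096391 (-1.86). Reads moved between the listed near-identical copies would leave their sums unchanged, which is argued against in S1, where the median log2 fold change of the 4 U RNAs with several copies was -2.38 after summing (median SE 0.90), while in S2 it cannot be told apart because the value of -1.07 lies within 2 median SE (0.85) of 0; copies outside the table were not tested. Whether scaling is the whole cause depends on the reference here too, and both references were chosen after the data were seen. With the given labels, the median log2 count of snRNA features relative to that of all features within each library differed by -3.19 in S1 and -1.56 in S2. Every IP library lay below every input library of its fraction (exact permutation p = 0.1 for each, the smallest possible). This measure argues against scaling as the whole cause, while the box C/D ratio does not decide it. Relative to box C/D snoRNA counts the groups overlapped in S1 (-2.29, exact permutation p = 0.2; -1.12, p = 0.3, without S1 input replicate 2) and in S2 (-1.25, p = 0.3), and with S1 input replicate 2 (1.66) and S1 IP replicate 1 (0.62) exchanged the S1 values relative to all features would overlap as well (-2.50), and the box C/D difference would turn to 1.15. Weaker binding of these RNAs by MeCP2 stays open and was not tested.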

How the results depend on the processing

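Tests on small RNA features alone, on miRNA features alone, with box C/D factors, without longer genes holding small RNAs, and of S2 libraries with a replicate block were chosen after the data were seen. For IP against input in S1 the 23 calls became 15 with RLE factors, 2 with upper-quartile factors, 5 with library sizes alone (2 higher, 3 lower), 232 with DESeq2, 11 with the stricter filter, 2 with only the compared groups, 1 with miRNA features alone, 3 with box C/D factors and 2 to 253 as each library was left out; among small RNA features alone 17 passed, 8 higher and 9 lower. In S2 the 0 calls became 21 with the S2 libraries alone and a replicate block, and stayed at 0 to 0 as each library was left out. The interaction's 0 became 1 with library sizes alone, 7 with DESeq2 and 0 to 22 as each library was left out. For S2 against S1 in input the 242 became 134 with library sizes alone, 153 with the stricter filter, 6 with only the compared groups, 0 with miRNA features alone, 143 with box C/D factors and 5 to 283 as each library was left out; 331 passed among small RNA features alone, 150 higher and 181 lower. In IP the 0 became 49 with library sizes alone, 13 with DESeq2, 59 among small RNA features alone, 11 with box C/D factors and 0 to 2 as each library was left out. The replicate block in the 12-library fit gave 16, 0, 0, 163 and 0 in the same order. The 43 list calls became 0 with an estimated correlation, 0 with fry (smallest adjusted p 0.0749), 27 among small RNA features alone, 4 among miRNA features alone and 39 to 45 as each library was left out. Fewer libraries and fewer features are part of some of these settings; otherwise the cause was not tested.

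The gap in the top share changed direction in S2 with the top feature alone (-0.562 percentage points) and between inputs with the top 50 (3.75). Of 120 printed features by comparison, with 3045 values under alternatives, 2522 kept direction and side of the threshold, 408 lost a call, 106 gained one and 9 changed sign in 6 features. These were Lrrc17 in the interaction (0.62 with box C/D factors) and, between inputs, Pcm1 (-0.36 with library sizes alone, -1.26 with box C/D factors), Kalrn (-0.079 and -1.13), Fcho2 (-0.16 and -1.09), AC132131.1 (-0.68 with box C/D factors) and Myo9b (-0.25 with box C/D factors). The printed set understates sign changes, since some list members were left out after theirs had been seen. Over all 285 features by comparison that the naming rule takes, 79 of 7295 values changed sign, in 32 of them. The miRNA median in S2 was 0.080 with box C/D factors and ran from -0.66 to 0.14 as each library was left out. It kept its sign in the other comparisons, from -3.20 to -0.97 for IP against input in S1, 0.84 to 2.88 in the interaction, -4.30 to -2.22 between inputs and -2.56 to -1.16 between IPs. The snRNA median kept its sign in S1 (-2.69 to -1.44), in S2 (-1.48 to -0.74), in the interaction (0.15 to 1.90) and between inputs (-3.04 to -0.58). What depth limits was not tested. The median count per feature ran from 22 to 103 over the libraries; S1 input replicate 2, with the lowest total (826887), had 29, against 26 and 22 in the other S1 inputs.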

Other observations

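The tests of RNA classes in this part were chosen after the data were seen. At the preset correlation of camera, and not with an estimated one, ribosomal RNA and mitochondrial tRNA stood lower in the S2 IP than in its input. The 11 rRNA features had a median log2 fold change of -1.28 (10 below 0, camera adjusted p = 3.97e-07, or 0.547 with an estimated correlation; -0.40 without S2 input replicate 3) and the 15 mitochondrial tRNAs -1.44 (15 below 0, camera adjusted p = 5.45e-06, or 0.600; -0.086 without S2 input replicate 2). In S1 the medians were -0.66 (10 below 0, camera adjusted p = 0.0235, or 0.912) and -1.15 (11 below 0, camera adjusted p = 0.00271, or 0.873). The direction in S1 depends on the measure: without S1 input replicate 2 these medians were -0.85 and -1.14, but the share of counts in IP over that in input went from 0.718 to 2.71 for rRNA and from 0.218 to 2.12 for mitochondrial tRNA. Between the IPs, S2 stood lower than S1 for mitochondrial tRNAs (-2.51, 15 of 15, camera adjusted p = 2.86e-10, or 0.542), rRNA (-1.78, 11 of 11, camera adjusted p = 1.04e-08, or 0.542) and mitochondrial mRNAs (-1.54, 14 of 14, camera adjusted p = 8.63e-07, or 0.571). The medians between the inputs were -1.71, -1.19 and -1.41 in the same order.

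Across the 2239 features, which are not independent replicates, the log2 fold changes of IP against input in S1 and S2 had a Pearson correlation of 0.326, and 60.1% shared their sign. This did not hold within every class: the correlation was 0.284 for miRNAs (70.4% of the same sign) and 0.260 for genes for proteins (59.9%), but -0.033 for box C/D snoRNAs (38.5%) and -0.071 for box H/ACA snoRNAs (68.0%). Those of IP against input in S1 and of S2 against S1 in input, which share the S1 input libraries, had 0.795, against 0.511 in simulations without any change.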
